A study of Mus musculus with 9 samples.

How the data were processed

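RNA levels were measured by bulk RNA-seq in 9 libraries of mouse adipocyte precursors from inguinal white adipose tissue, 3 each from non-induced cells (day 0) and from cells after 4 and 8 days of beige differentiation. Per the labels' protocols, cells were lysed in a buffer with cycloheximide, which arrests ribosomes, and the detergent Triton X-100, the lysate was cleared by centrifugation, and RNA of the supernatant was used, so the measurement favours cytoplasmic transcripts. Libraries were made with a stranded total RNA kit that removes ribosomal RNA, per the labels' protocols, so transcripts without a poly(A) tail can be counted too. Groups and replicate numbers were taken from the labels.

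The authors deposited a table of raw counts of reads per Ensembl gene, with 1 column per library and no normalization. Reads were aligned with HISAT2 to genome build GRCm39 and counted with featureCounts, per the submitters' processing notes. The versions, the strand setting and the annotation release were not given in the sources used here, so counts of overlapping or antisense genes are uncertain, as are those of genes that share reads with near-identical copies, such as class I histocompatibility genes, ribosomal proteins with processed pseudogenes, mitochondrial genes with nuclear copies, and the Ifit family. The table held 55359 genes, of which 30671 had no count in any library. Gene symbols were looked up by Ensembl ID; 3 symbols of the lists were given to more than 1 ID, and the ID with the highest total was used. The reference at hand was GENCODE M21, of another genome build, so no coordinates were taken from it; it served only for lengths, GC content and gene types of the 52083 IDs (94.1%) it shares with the table. The genes drawn in the plot of expression by day were Adipoq (ENSMUSG00000022878), Ucp1 (ENSMUSG00000031710), Cidea (ENSMUSG00000024526), Acta2 (ENSMUSG00000035783), Fkbp5 (ENSMUSG00000024222), Ifit3 (ENSMUSG00000074896), Gdf15 (ENSMUSG00000038508) and Ccna2 (ENSMUSG00000027715).

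Total counts per library ranged from 26387408 to 31474490. A floor of 3 counts in a single library corresponds to 0.0809 to 0.125 CPM. No pair of libraries of a day differed by as little as sampling noise, with chi-square per degree of freedom from 16.1 to 234, so all were kept as separate replicates.

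Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept with filterByExpr (minimum count 10, minimum total count 15), which left 14649. All 9 libraries entered 1 quasi-likelihood fit of edgeR with TMM scaling and no covariates, leaving 6 residual degrees of freedom; the biological coefficient of variation was 22.7% (common dispersion 0.0515). Each of the 3 comparisons used a two-sided F-test with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM values use the TMM-scaled library sizes, and all gene p-values in the text come from edgeR unless DESeq2 is named. Log2 fold changes are those of the edgeR fit. Where every library of a group had 0 counts, the fold is a lower bound against 3 counts over the group, and with 1 to 3 counts the ratio has a 95% counting interval. Principal components were computed from log2 CPM with a prior count of 2, and the plot of genes by day uses log2(CPM + 0.1).

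The design, the tests, the alternatives, 35 gene lists with 781 genes and the rule for naming genes were chosen before the data were examined. The lists were thermogenic genes, adipocyte genes, preadipocyte and progenitor genes, fibrillar extracellular matrix, basement membrane, contractile and myofibroblast genes, cell cycle, nuclear-encoded oxidative phosphorylation, mitochondrially encoded proteins, tricarboxylic acid cycle and pyruvate dehydrogenase, mitochondrial fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, glycolysis, branched-chain amino acid breakdown, peroxisome, creatine, calcium and other energy-dissipating cycles, ATF4 and integrated stress response targets, cytosolic aminoacyl-tRNA synthetases, cytosolic and mitochondrial ribosomal proteins, translation initiation and elongation factors, ribosome biogenesis, endoplasmic reticulum chaperones, glucocorticoid targets, interferon response, inflammatory cytokines and acute phase genes, and markers of macrophages, endothelium, mural cells, lymphocytes, mesothelium, Schwann cells, skeletal muscle and mammary epithelium. The 32 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over 96 tests. No list passed in any comparison when camera estimated the correlation between genes; 7, 6 and 4 lists had an unadjusted p under 0.05 then in day 4 against day 0, day 8 against day 0 and day 8 against day 4. Limma's fry, which tests whether the members move one way on balance and does not compare them with other genes, called 26, 22 and 11 lists.

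The text could name preset genes, up to 4 members of each list with the largest change among those past the threshold, the 8 largest rises and 8 largest falls with at least 10 CPM in the higher group and no overlap between libraries, and 5 genes per class of change in both intervals. The rule took list members at a mean of at least 1 CPM in the higher group. Members named beside counts of 5 or fewer, and the most abundant markers of other cell types, fall partly outside that rule and were chosen after their values were seen.

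The alternatives were DESeq2's size factors, total counts, no filter on low counts, the replicate number as a block, each library left out in turn, DESeq2's Wald test, fits of only the 6 libraries compared, edgeR's glmTreat against a fold change of 2, an estimated correlation and fry. Counts of list members without day 4 replicate 2 were added after that library was seen to stand apart, and calls of single list members under each setting, and bounds and ratios over 0 to 3 counts without each library, after the data were seen. The tests were tried on simulated counts with 200 changed genes, fewer than were called, so recovery may differ here. Of 50 genes each at folds of 1.5, 2, 4 and 8, edgeR recovered 8%, 46%, 90% and 100% at day 4 against day 0. Among all 14320 genes it called 0.0212% of unchanged ones. At day 8 against day 0 it recovered 6%, 54%, 94% and 100% at these folds. At day 8 against day 4 it recovered 66% at 2.25-fold, 90% at 4-fold and 100% at 16-fold. Among 14322 simulated genes, camera called the 1 changed list in both comparisons with day 0, and 0 of 20 unchanged lists in each of the 3. Between days 4 and 8 that list was simulated with no change and was not called, so recovery of a changed list was not tested there. Single results of a few list members and named genes are not reported here, so some counts of list members are given in 1 direction only.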

Results

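RNA was sequenced from adipocyte precursors of mouse inguinal white adipose tissue, a subcutaneous fat depot, that were driven toward beige adipocytes, fat cells able to burn fuel for heat. There were 9 libraries, 3 from cells before induction (day 0), 3 from day 4 and 3 from day 8 of differentiation. The induction medium held the glucocorticoid dexamethasone, the phosphodiesterase inhibitor IBMX, indomethacin, insulin, the thyroid hormone triiodothyronine and rosiglitazone, an agonist of the adipogenic receptor PPARγ. Dexamethasone, IBMX and indomethacin were left out of the medium after 2 days. The RNA came from the cleared supernatant of a detergent lysate, so nuclear transcripts can be under-represented in every library. Total counts per library ranged from 26387408 to 31474490 at day 0, from 27222642 to 27692241 at day 4 and from 30118228 to 31006682 at day 8. Of the 55359 listed genes, 14649 had enough counts to be tested. Values below are CPM, the counts of a gene per 1e6 counts of the TMM-adjusted total of its library, given as mean ± SD with n = 3 libraries per day, and log2 fold changes with their standard error (SE). The labels do not say that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. Counting intervals and floors cover counting error only. Members named beside counts of 5 or fewer were chosen after their values were seen.

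The first principal component, which held 75.7% of the variance between libraries, separated day 0 from days 4 and 8, and the second, with 12.5%, set day 4 apart from day 8. Scores on the first component were -138, -135 and -138 at day 0 and 78.7, 92.0 and 72.7 at day 8. At day 4 replicates 1 and 3 scored 84.6 and 69.5, and replicate 2 stood apart at 13.7, between day 0 and the other day 4 libraries. The share of counts from genes encoded in the mitochondrial genome was 1.59% ± 0.124 at day 0, 4.40% ± 1.24 at day 4 and 6.2% ± 1.96 at day 8.

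**Figure D1:**
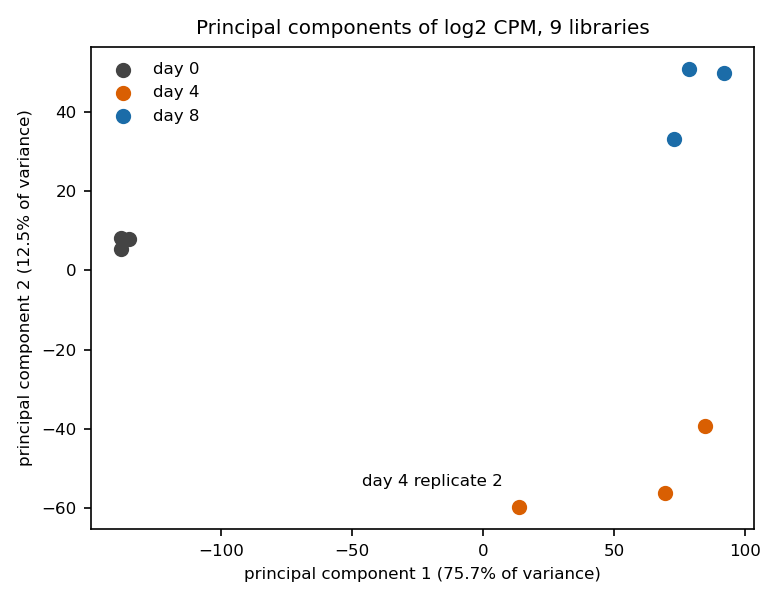
First against second principal component of log2 CPM over the tested genes, with 1 point per library coloured by day and axis labels giving the percent of variance. Day 4 replicate 2 scored 13.7 on the first component, against 84.6 and 69.5 for the other day 4 libraries.

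The first comparison asked what had changed by day 4 of differentiation. All 21 tested genes of fat cells rose (adjusted p = 2.39e-63; adjusted p = 0.15 with an estimated correlation). Adipoq, which encodes the hormone adiponectin, went from 0.0216 ± 0.0374 CPM at day 0 to 2168 ± 540.4 CPM at day 4. This was a ratio of 109000 over 2 counts at day 0 with a 95% counting interval of 30200 to 901000. The ratio was 69300 without day 0 replicate 1, and without day 0 replicate 2, which held both counts, Adipoq was at least 51200-fold higher. Ucp1, the uncoupling protein through which thermogenic fat cells release heat, had no counts at day 0 and 6.71 ± 4.66 CPM at day 4, at least 228-fold higher than the floor of 3 counts over the day 0 group (138 without day 4 replicate 1 and 145 without day 0 replicate 1, where the floor is over fewer counts). All 15 contractile genes went the other way (adjusted p = 0.436 with an estimated correlation), with smooth muscle actin Acta2 falling from 2452 ± 361 to 108 ± 129.9 CPM. Interferon response genes fell in 13 of 16 cases (adjusted p = 0.554 with an estimated correlation), and known glucocorticoid targets rose in 11 of 12 (adjusted p = 0.15 with an estimated correlation).

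Of 14649 genes tested with edgeR, 7998 (54.6%) changed between day 0 and day 4. Of these 4192 were higher and 3806 lower at day 4, and 2721 and 2348 changed by at least 2-fold. Without day 4 replicate 2 there were 9110, 4560 higher and 4550 lower. Scaling by total counts moved the median log2 fold change over all tested genes from -0.012 to -0.336. It gave 8704 changed genes, of which 35.3% were higher at day 4 against 52.4% with TMM scaling. Genes with the largest falls included Ccn3, a matricellular protein (1242 ± 92.0 to 13.5 ± 11.0 CPM, log2 fold change -6.52, SE 0.65, adjusted p = 1.66e-05). Others were Kif26b, a kinesin (-6.66, SE 0.57, adjusted p = 6.07e-06), and Cxcl14, a chemokine (-6.28, SE 0.48, adjusted p = 2.65e-06). These values were -7.38 for Ccn3, -7.80 for Kif26b and -7.17 for Cxcl14 without day 4 replicate 2.

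All 21 tested adipocyte genes rose by day 4. The median log2 fold change was 9.08 (camera, adjusted p = 2.39e-63; adjusted p = 0.15 with an estimated correlation). The transcription factors Pparg (14.3 ± 5.23 to 156 ± 40.3 CPM, 3.45, SE 0.29, adjusted p = 5.66e-06) and Cebpa, which drive adipogenesis, were among them. Cebpa went from 47.3 ± 1.45 to 1299 ± 272.7 CPM (4.78, SE 0.22, adjusted p = 1.2e-07). The fatty acid carrier Fabp4 reached 18620 ± 5897 CPM from 18.2 CPM at day 0. Of 17 thermogenic genes tested 14 rose and 1 fell, the fatty acid carrier Fabp3. The Fabp3 call did not pass without any one day 0 library, day 4 replicate 1 or 3 or day 8 replicate 1 (adjusted p from 0.0561 to 0.122). The thermogenic median was 5.04 (adjusted p = 2.83e-11, or 0.227 with an estimated correlation). Cox8b, a cytochrome oxidase subunit, was at least 864-fold higher (549 without day 0 replicate 1). Kcnk3, a potassium channel, rose from 0.173 ± 0.0607 to 207.5 ± 48.6 CPM (10.17, SE 0.38, adjusted p = 4.15e-08). Prdm16, a regulator of brown and beige fat identity, stood at 5.46 ± 1.21 and 6.67 ± 0.406 CPM (0.29, SE 0.21, adjusted p = 0.269). With 18 members tested, the thermogenic median was 6.18 without day 4 replicate 2 and between 5.74 and 5.90 without any one day 0 or day 8 library. Both medians were the same with the genes at 0 counts placed at their bounds.

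Genes of mitochondria and fuel use rose together. All 75 nuclear genes of oxidative phosphorylation rose (median 2.44, adjusted p = 7.74e-32, or 0.436 with an estimated correlation). Among them were cytochrome c, Cycs, from 42.8 ± 5.08 to 813 ± 289.1 CPM (4.25, SE 0.28, adjusted p = 1.12e-06), and the complex III subunit Uqcrfs1 (3.75, SE 0.26, adjusted p = 1.26e-06). Of 13 genes encoded in the mitochondrial genome 12 rose, with a median of 2.27 (adjusted p = 0.00164, or 0.573 with an estimated correlation). All 19 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase rose (median 2.88, adjusted p = 2.68e-20, or 0.261 with an estimated correlation). The largest rise was that of pyruvate carboxylase, Pcx (18.7 ± 1.39 to 1568 ± 576.3 CPM). Mitochondrial fatty acid oxidation had 17 of 18 genes higher, such as the dehydrogenase Acadm (4.52, SE 0.26, adjusted p = 4.51e-07), and 1 lower, Cpt1a, the liver-type carnitine palmitoyltransferase. The list's median was 3.07 (adjusted p = 1.48e-20, or 0.212 with an estimated correlation). All 18 peroxisome genes rose (median 2.80, adjusted p = 6.89e-21, or 0.212 with an estimated correlation). So did 19 of 20 genes of branched-chain amino acid breakdown (median 2.33, adjusted p = 7.67e-15, or 0.306 with an estimated correlation). Of 76 mitochondrial ribosomal protein genes 74 rose (median 1.44, adjusted p = 1.81e-22, or 0.452 with an estimated correlation).

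Fatty acid synthesis had 12 of 16 genes higher and 1 lower, the elongase Elovl5. Its median was 3.27 (adjusted p = 4.71e-10, or 0.23 with an estimated correlation). The desaturase Scd1 rose from 303.2 ± 33.7 to 16600 ± 8725 CPM. Mlxipl, a glucose-sensing activator of lipogenic genes, rose from 0.0979 ± 0.0441 to 44.4 ± 15.3 CPM (8.76, SE 0.45, adjusted p = 2.43e-07). In glycolysis 15 of 18 genes rose and 1 fell, the hexokinase Hk1. The Hk1 call did not pass with no filter on low counts (adjusted p = 0.0655) or without day 0 replicate 2 (0.0654), day 0 replicate 3 (0.0527) or day 4 replicate 3 (0.0542). The glycolysis list had a median of 1.59 (adjusted p = 0.00264, or 0.724 with an estimated correlation). Glucocorticoid targets rose in 11 of 12 cases (median 1.89, adjusted p = 2.74e-08, or 0.15 with an estimated correlation). Fkbp5, a co-chaperone of the glucocorticoid receptor, rose from 31.2 ± 4.71 to 374 ± 12.2 CPM (3.58, SE 0.23, adjusted p = 8.47e-07). The transcriptional repressor Zbtb16 was at least 1210-fold higher (769 without day 0 replicate 1).

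All 15 contractile and myofibroblast genes fell (median -3.37, adjusted p = 2.47e-08, or 0.436 with an estimated correlation). In day 4 replicate 2, which stood apart, Acta2 was at 258 CPM against 26.7 and 39.8 in the other day 4 libraries. Leaving it out gave a list median of -4.09. The log2 fold change then was -6.2 in place of -4.50 (SE 0.75, adjusted p = 0.000554) for Acta2 and -5.46 in place of -4.54 (SE 0.49, adjusted p = 2.74e-05) for the myosin light chain Myl9. Fibrillar matrix genes fell in 16 of 25 cases and rose in 3, the collagen VI chains Col6a1, Col6a2 and Col6a3 (Col6a3 did not pass with total counts, adjusted p = 0.0501). The matrix list had a median of -1.08 (adjusted p = 0.000537, or 0.674 with an estimated correlation). Thbs2, a matrix glycoprotein, fell from 2352 ± 124.3 to 291 ± 109.4 CPM (-3.01, SE 0.26, adjusted p = 5.79e-06). Col1a1, the main collagen I chain, fell from 15130 ± 1431 to 4807 ± 1835 CPM (-1.65, SE 0.30, adjusted p = 0.000864). Of 16 preadipocyte and progenitor genes 10 fell and 3 rose, Cd34, Dlk1 and Ly6a. With total counts Dlk1 (adjusted p = 0.0969) and Ly6a (0.102) did not pass. Cd34 did not pass without day 0 replicate 1 (0.0567), day 0 replicate 2 (0.0675) or day 4 replicate 3 (0.0532). Dlk1 did not without day 0 replicate 1 (0.0722), day 0 replicate 2 (0.0931) or day 4 replicate 2 (0.0782), nor Ly6a without day 0 replicate 2 (0.0618) or day 0 replicate 3 (0.0668). The median here was -1.40 (adjusted p = 0.0463, or 0.724 with an estimated correlation). That call did not pass without day 0 replicate 3 (adjusted p = 0.0562), day 4 replicate 1 (0.0826), day 4 replicate 3 (0.0698) or day 8 replicate 1 (0.0621), or with total counts (0.139).

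Cell cycle genes fell in 19 of 27 cases (median -0.82, adjusted p = 0.00334, or 0.709 with an estimated correlation). Among them were Ccna2, the cyclin of S phase, from 17.5 ± 1.51 to 7.51 ± 2.46 CPM (-1.22, SE 0.30, adjusted p = 0.00557), and the proliferation marker Mki67 (-1.25, SE 0.31, adjusted p = 0.00591). The count was 11 without day 4 replicate 1 and 10 without day 4 replicate 3. Interferon response genes fell in 13 of 16 cases (median -1.85, adjusted p = 0.00419, or 0.554 with an estimated correlation). Oasl2, an antiviral protein, fell from 22.4 ± 3.84 to 5.71 ± 2.92 CPM (-1.97, SE 0.32, adjusted p = 0.00044). Ifit2, which binds foreign RNA, fell from 8.53 ± 1.13 to 1.42 ± 0.433 CPM (-2.58, SE 0.39, adjusted p = 0.000265).

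The other lists did not pass the camera test at day 4 against day 0. Medians were 0.34 for basement membrane (6 higher, 2 lower of 12; adjusted p = 0.455), 0.49 for cholesterol synthesis (11 higher, 2 lower of 21; adjusted p = 0.166) and -0.93 for creatine, calcium and other energy-dissipating cycles (1 higher, 4 lower of 7; adjusted p = 0.318). They were -0.08 for ATF4 and integrated stress response targets (8 higher, 8 lower of 26; adjusted p = 0.557), -0.43 for endoplasmic reticulum chaperones (2 higher, 9 lower of 18; adjusted p = 0.118) and -1.76 for inflammatory cytokines and acute phase genes (4 higher, 8 lower of 14; adjusted p = 0.435). Fry, which asks only whether members move one way, called basement membrane, cholesterol synthesis, translation factors and ribosome biogenesis as higher and the energy-dissipating cycles and chaperones as lower (adjusted p from 0.00372 to 0.0357). With total counts the medians were 0.01 for basement membrane, 0.16 for cholesterol synthesis (7 higher, 9 lower), -0.41 for ATF4 targets and -0.76 for chaperones (15 lower). When day 4 replicate 2 was left out they were 0.10 for basement membrane (6 higher, 4 lower), 0.03 for ATF4 targets and -0.03 for ribosomal proteins. Cholesterol synthesis passed with no filter on low counts (median 0.48, adjusted p = 0.0342). The inflammatory list had a median of -2.91 and an adjusted p of 0.0361 without day 4 replicate 2. In the translation machinery, 4 lists had medians near 0 whose sign turned with total counts, 0.16 to -0.17 for initiation and elongation factors (13 higher, 1 lower of 40; adjusted p = 0.643) and 0.21 to -0.12 for ribosome biogenesis (12 higher, 3 lower of 28; adjusted p = 0.549). The others went from 0.08 to -0.24 for cytosolic ribosomal proteins (3 higher, 1 lower of 79; adjusted p = 0.848) and 0.07 to -0.26 for cytosolic aminoacyl-tRNA synthetases (4 higher, 7 lower of 20; adjusted p = 0.612). For the ribosomal proteins and the synthetases camera's direction was down while the median was above 0, and the synthetases' mean was -0.03. Adjusted over the list alone, the counts of changed members were the same for the adipocyte, thermogenic, contractile, preadipocyte, oxidative phosphorylation, tricarboxylic acid cycle, both fatty acid, branched-chain amino acid, peroxisome and glucocorticoid lists. They were 13 for genes of the mitochondrial genome, 75 for mitochondrial ribosomal proteins, and 16 higher and 1 lower for glycolysis. For the remaining lists they were 3 higher and 19 lower for fibrillar matrix, 21 lower for cell cycle and 14 lower for interferon response. The lists that did not pass had the same counts, adjusted over the list alone, but for 3 lower in basement membrane, 3 lower in cholesterol synthesis, 5 lower in the energy-dissipating cycles, 10 lower chaperones, 12 higher translation factors, and 1 higher and 0 lower ribosomal proteins.

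**Figure D2:**
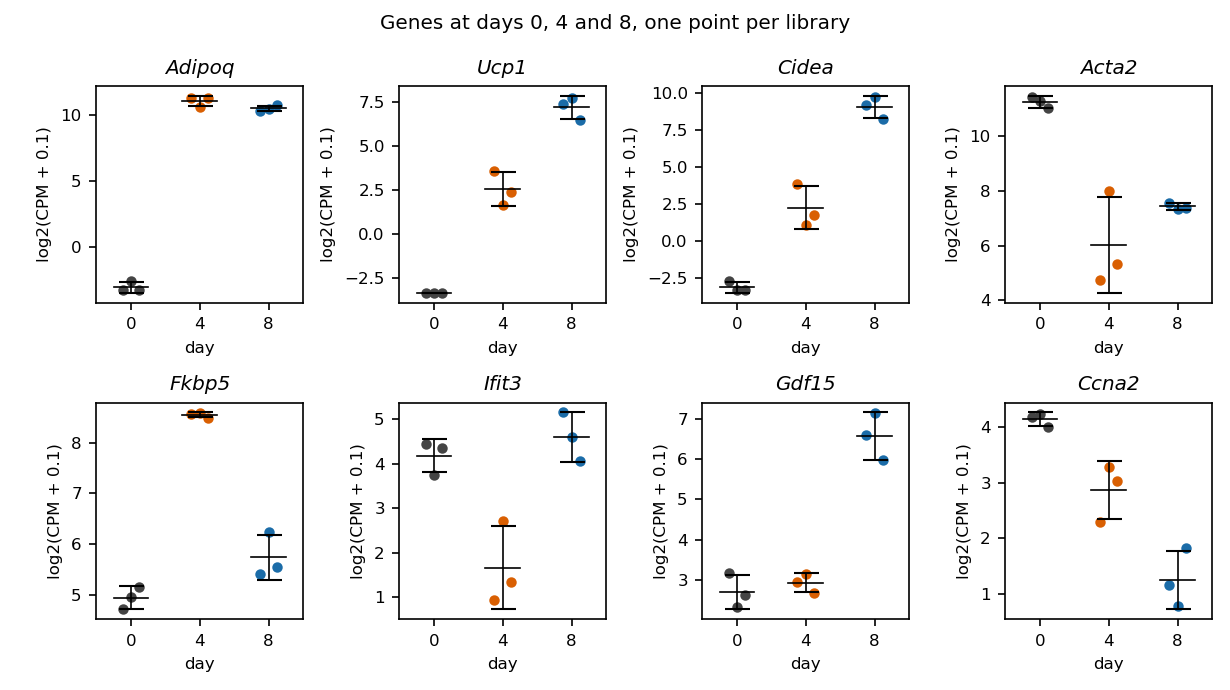
Expression of 8 genes as log2(CPM + 0.1) at days 0, 4 and 8, with 1 point per library and bars at the mean ± SD of the 3 libraries of a day. Adipoq reached 2168 CPM by day 4, Cidea 575 CPM by day 8, and Fkbp5 stood at 374 CPM at day 4 and 55.3 CPM at day 8.

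The second comparison set day 8 against day 0, over the whole course. Of 17 thermogenic genes 15 were higher than at day 0 (adjusted p = 0.212 with an estimated correlation), with Ucp1 at 156 ± 62.3 CPM, at least 5300-fold above the day 0 floor of 3 counts over the group (3370 without day 0 replicate 1). Cidea, a lipid droplet protein of brown and beige fat, stood at 575 ± 272 CPM. Its ratio to day 0 was 29000 over 2 counts at day 0 with a counting interval of 8020 to 239000. That ratio was 19300 without day 0 replicate 3, and without day 0 replicate 1, which held both counts, Cidea was at least 12400-fold higher. All 21 adipocyte and all 75 nuclear oxidative phosphorylation genes were higher, and 26 of 27 cell cycle and 22 of 25 fibrillar matrix genes lower (adjusted p from 0.15 to 0.525 with an estimated correlation). Stress-responsive Gdf15, a circulating cytokine, was higher at day 8, at 100.3 ± 39.3 against 6.64 ± 2.06 CPM (3.91, SE 0.32, adjusted p = 4.43e-06).

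At day 8, 9290 genes (63.4%) differed from day 0, 4913 higher and 4377 lower, with 3298 and 2887 changed by at least 2-fold. Without day 4 replicate 2, which then shares only in the estimate of spread and scaling, there were 10111, 5037 higher and 5074 lower. With total counts, where the median log2 fold change over all tested genes was -0.332 in place of 0.028, there were 9676. Of these 37.5% were higher at day 8, against 52.9%. Tmem45b, a transmembrane protein, was at least 4650-fold higher at day 8, and Ffar4, a receptor for long-chain fatty acids, at least 6290-fold (2960 and 4000 without day 0 replicate 1). Ptn, a growth factor, fell from 575.5 ± 111.2 to 5.35 ± 2.48 CPM (-6.74, SE 0.73, adjusted p = 2.43e-05).

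All 21 adipocyte genes (median 9.47, adjusted p = 3.32e-53; adjusted p = 0.15 with an estimated correlation; median 8.73 over 22 genes with no filter) and 15 of 17 thermogenic genes (median 6.21, adjusted p = 2.64e-13; adjusted p = 0.212 with an estimated correlation) were higher at day 8 than at day 0. Prdm16 stood at 6.92 ± 0.758 CPM (0.34, SE 0.21, adjusted p = 0.178). All 75 nuclear oxidative phosphorylation genes were higher. Their median was 2.87 (adjusted p = 1.43e-36, or 0.387 with an estimated correlation). Also higher were 12 of 13 genes of the mitochondrial genome (median 2.63, adjusted p = 0.00138, or 0.573 with an estimated correlation). The list of the tricarboxylic acid cycle (19 of 19, median 3.18, adjusted p = 3.07e-18, or 0.261 with an estimated correlation) rose in full. Peroxisome genes did as well (18 of 18, median 2.36, adjusted p = 4.11e-17, or 0.212 with an estimated correlation). So did branched-chain amino acid breakdown (20 of 20, median 2.27, adjusted p = 7.15e-12, or 0.331 with an estimated correlation). Glycolysis rose in full too (18 of 18, median 2.29, adjusted p = 6.55e-07, or 0.538 with an estimated correlation). Fatty acid oxidation had 17 genes higher and Cpt1a lower (median 3.39, adjusted p = 1.56e-18, or 0.212 with an estimated correlation). Fatty acid synthesis had 12 of 16 higher and Elovl5 lower (median 2.61, adjusted p = 2.47e-08, or 0.261 with an estimated correlation). Mitochondrial ribosomal proteins had 75 of 76 higher (median 1.72, adjusted p = 1.17e-23, or 0.436 with an estimated correlation). Ldhb, a lactate dehydrogenase subunit, rose from 25.9 ± 1.31 to 488.5 ± 118.9 CPM (4.24, SE 0.26, adjusted p = 6.61e-07).

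Cell cycle genes were lower in 26 of 27 cases (median -1.89, adjusted p = 2.47e-08, or 0.436 with an estimated correlation). Ccna2 stood at 2.40 ± 0.933 CPM (-2.86, SE 0.32, adjusted p = 3.03e-05), and the replication helicase subunit Mcm5 at 2.41 ± 0.721 against 16.8 ± 2.80 CPM (-2.80, SE 0.28, adjusted p = 1.51e-05). Fibrillar matrix genes were lower in 22 of 25 cases and higher in 2, Col6a1 and Col6a2 (median -2.04, adjusted p = 3.18e-07; adjusted p = 0.525 with an estimated correlation). With total counts neither Col6a1 (adjusted p = 0.0973) nor Col6a2 (0.279) passed, and Col6a2 did not without day 0 replicate 1 (0.0721), day 0 replicate 2 (0.0924) or day 8 replicate 3 (0.106). All 15 contractile genes (median -3.20, adjusted p = 1.99e-06, or 0.538 with an estimated correlation) were lower. Of the preadipocyte genes 11 of 16 were lower (median -1.88, adjusted p = 0.00312, or 0.613 with an estimated correlation). These included the platelet-derived growth factor receptor Pdgfrb (836 ± 44.0 to 114 ± 5.90 CPM, -2.87, SE 0.41, adjusted p = 0.00014). Glucocorticoid targets were higher in 10 of 12 cases and lower for the kinase Sgk1 (median 0.89, adjusted p = 0.00264; adjusted p = 0.306 with an estimated correlation). With total counts 6 were higher and 1 lower (median 0.52, adjusted p = 0.00201). Cytosolic ribosomal protein genes were lower in 20 of 79 cases, and those higher included Rpl36 and Rplp2. With total counts Rpl36 (adjusted p = 0.144) and Rplp2 (0.175) did not pass, nor did Rplp2 without day 0 replicate 1 (0.0508) or day 0 replicate 3 (0.0637). The ribosomal median was -0.22 (camera, adjusted p = 0.0425, or 0.88 with an estimated correlation and 0.22 with fry), and with total counts it was -0.59 with 55 lower (adjusted p = 0.00454). Counts of such genes can share reads with processed pseudogenes. The ribosomal protein call did not pass without day 0 replicate 2 (adjusted p = 0.0863), day 4 replicate 1 (0.076), day 4 replicate 3 (0.0594), day 8 replicate 1 (0.25, median -0.09) or day 8 replicate 3 (0.0782). The median was -0.37 without day 8 replicate 2.

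The remaining lists did not pass with camera at day 8 against day 0, while fry called ATF4 targets (adjusted p = 0.00154), chaperones (0.00718), cholesterol synthesis (0.035) and synthetases (0.0452) as higher. Medians were -0.42 for basement membrane (3 higher, 6 lower of 12; adjusted p = 0.607), -0.33 for the energy-dissipating cycles (2 lower of 7, Gatm and Slc6a8; adjusted p = 0.554) and 0.46 for interferon response (6 higher, 3 lower of 16; adjusted p = 0.709). The Gatm call did not pass with no filter (adjusted p = 0.0759), with DESeq2 (0.0578) or without day 0 replicate 1 or 2, day 4 replicate 1 or 3, or day 8 replicate 1 or 3 (0.0511 to 0.144), and its log2 fold change was -2.92 in place of -1.80 without day 8 replicate 2. List medians were -1.24 for inflammatory cytokines (3 higher, 7 lower of 14; adjusted p = 0.415) and -0.13 for ribosome biogenesis (4 higher, 7 lower of 28; adjusted p = 0.471). ATF4 targets had a median of 0.55 with 12 of 26 higher and 5 lower (adjusted p = 0.0848). The adjusted p was 0.00525 with no filter on low counts, 0.0382 without day 4 replicate 2, 0.0394 without day 8 replicate 3 and up to 0.132, without day 8 replicate 1, and with total counts the median was 0.18 (0.101). Other medians with total counts were -0.78 for basement membrane, -0.69 for the energy-dissipating cycles (4 lower), 0.10 for interferon response and -0.49 for ribosome biogenesis (1 higher, 15 lower). The medians of 4 lists turned sign with total counts, 0.12 to -0.25 for cholesterol synthesis (10 higher, 4 lower of 21; adjusted p = 0.607) and 0.15 to -0.22 for aminoacyl-tRNA synthetases (9 higher, 3 lower of 20; adjusted p = 0.848). The remaining medians went from 0.17 to -0.19 for initiation and elongation factors (14 higher, 8 lower of 40; adjusted p = 0.878) and 0.34 to -0.03 for endoplasmic reticulum chaperones (9 higher, 2 lower of 18; adjusted p = 0.39). Adjusted over the list alone, the counts of the lists that passed were the same but for 11 glucocorticoid targets higher and 1 lower, and 3 ribosomal protein genes higher and 16 lower. Among lists that did not pass, counts so adjusted differed for the energy-dissipating cycles (1 lower) and ATF4 targets (15 higher, 5 lower). They also differed for translation factors (14 higher, 7 lower), ribosome biogenesis (4 higher, 6 lower) and interferon response (5 higher, 2 lower). Macrophages had 0, with 5 lower at an unadjusted p under 0.05 and 3 with DESeq2.

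**Figure D3:**
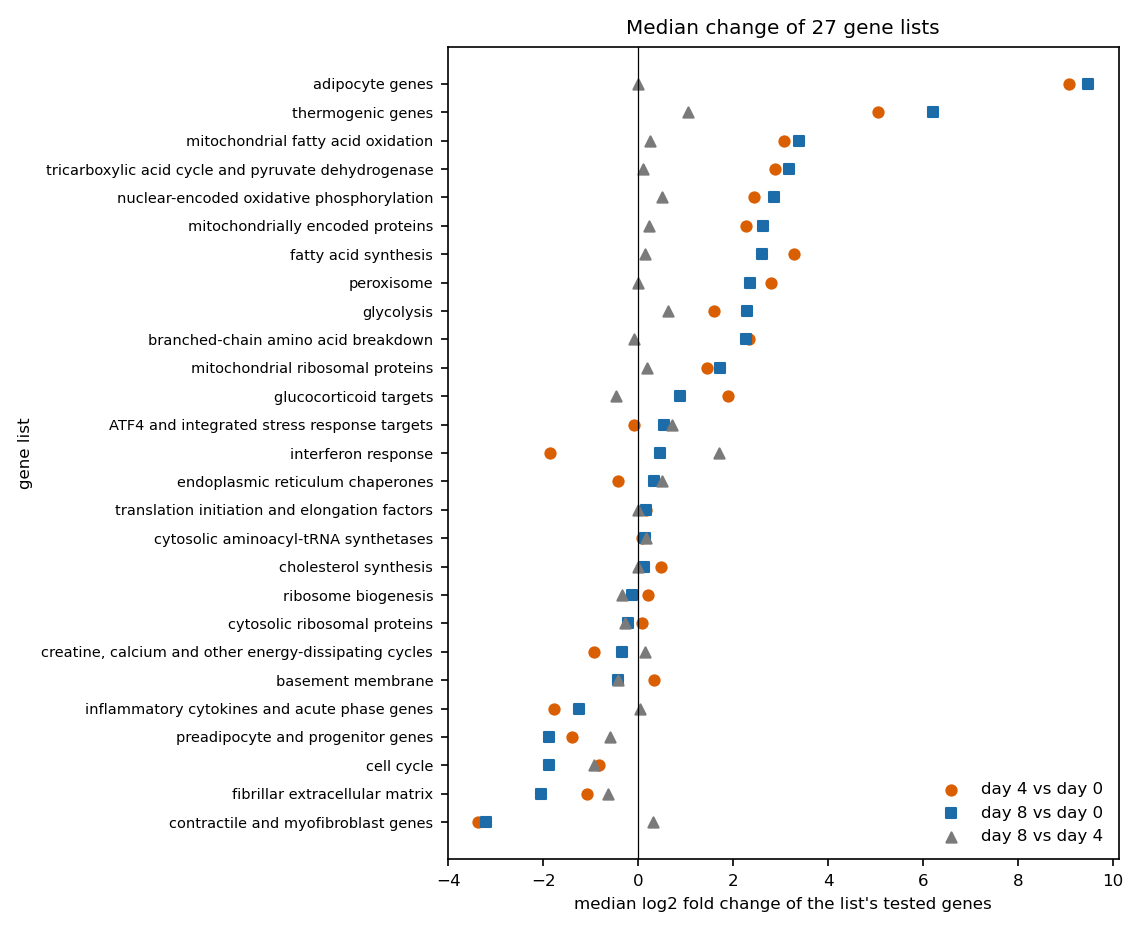
Median log2 fold change of the tested members of 27 gene lists, with 1 row per list and 1 symbol per comparison. The adipocyte list had the highest median against day 0, 9.08 at day 4 and 9.47 at day 8, and a median of -0.01 between days 4 and 8; signs of the medians near 0 turn with total counts for cholesterol synthesis, peroxisome, tRNA synthetase, ribosomal protein, translation factor, ribosome biogenesis, chaperone and cytokine lists in at least 1 comparison.

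The third comparison asked what changed between day 4 and day 8, and so whether the effects at the 2 times against day 0 differ. Thermogenic genes rose in 9 of 17 cases (adjusted p = 0.436 with an estimated correlation), with Cidea from 6.61 ± 6.82 to 575 ± 272 CPM (6.45, SE 0.74, adjusted p = 0.000504) and Ucp1 from 6.71 ± 4.66 to 156 ± 62.3 CPM (4.54, SE 0.53, adjusted p = 0.00128). Glucocorticoid targets fell in 5 of 12 cases (adjusted p = 0.192 with an estimated correlation), Fkbp5 from 374 ± 12.2 to 55.3 ± 18.0 CPM (-2.76, SE 0.22, adjusted p = 0.000133). Interferon response genes rose in 13 of 16 cases, ATF4 targets in 12 of 26 and endoplasmic reticulum chaperones in 9 of 18 (adjusted p = 0.212 with an estimated correlation for each list). Gdf15 went from 7.6 ± 1.24 to 100.3 ± 39.3 CPM (3.72, SE 0.32, adjusted p = 2e-04). The endoplasmic reticulum chaperone Hspa5 rose from 332 ± 35.3 to 954 ± 194.7 CPM (1.52, SE 0.17, adjusted p = 0.000491). Cell cycle genes fell in 18 of 27 cases (adjusted p = 0.436 with an estimated correlation). Without day 4 replicate 1 the values were 7.74 for Cidea and 5.26 for Ucp1.

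Between day 4 and day 8, 3285 genes (22.4%) changed. Of these 1709 were higher and 1576 lower at day 8, and 853 and 767 changed by at least 2-fold. Without day 4 replicate 2 there were 3391, 1644 higher and 1747 lower. The count was 1894 (910 higher, 984 lower) without day 4 replicate 3, 2107 (951 lower) without day 8 replicate 1 and 2012 (1083 higher, 929 lower) without day 8 replicate 2. It was 1901 (947 higher, 954 lower) when the fit held only the 6 libraries compared. The largest rises included Mreg, a regulator of lysosome transport (3.76 ± 0.335 to 78.1 ± 2.97 CPM, 4.38, SE 0.15, adjusted p = 2.84e-07). Others were Cdsn, an adhesion protein of skin (4.79 ± 1.23 to 166 ± 12.9 CPM, 5.11, SE 0.28, adjusted p = 1.41e-05), and Derl3, a factor of endoplasmic reticulum-associated degradation (0.478 ± 0.246 to 11.1 ± 2.77 CPM, 4.52, SE 0.42, adjusted p = 0.000249). The largest falls included the microtubule-associated protein Map7d2 (59.1 ± 11.0 to 1.31 ± 0.461 CPM, -5.49, SE 0.28, adjusted p = 8.67e-06).

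Thermogenic genes rose in 9 of 17 cases (median 1.05, adjusted p = 3.7e-05; adjusted p = 0.436 with an estimated correlation). Among them was the proton channel Otop1 (2.22 ± 1.19 to 21.1 ± 5.81 CPM, 3.25, SE 0.43, adjusted p = 0.00205). With 18 members tested, the median was 0.56 without day 4 replicate 2. The adipocyte list as a whole did not pass (median -0.01, adjusted p = 0.709). Pck1, of glyceroneogenesis (10.7 ± 4.78 to 62.1 ± 11.3 CPM, 2.54, SE 0.32, adjusted p = 0.000765), and Trarg1, a regulator of glucose transporter traffic, rose. Acsl1, Cebpa, Gpd1 and the lipid droplet protein Cidec fell (Cidec 6503 ± 1864 to 2486 ± 269 CPM, -1.39, SE 0.26, adjusted p = 0.00502). Acsl1 did not pass without day 4 replicate 3 (adjusted p = 0.0512), Cebpa without day 4 replicate 3 (0.0945), day 8 replicate 1 (0.0839) or day 8 replicate 3 (0.0533), and Gpd1 without day 0 replicate 3, day 4 replicate 3 or any one day 8 library (0.0568 to 0.123). In the fit of only the 6 libraries compared Cebpa (0.0734) and Gpd1 (0.0831) did not pass. The adipocyte list's median was -0.29 without day 4 replicate 2 (adjusted p = 0.00765) and 0.21 without day 4 replicate 1 (0.651). Glycolysis genes rose in 6 of 18 cases (median 0.62, adjusted p = 2.01e-06, or 0.554 with an estimated correlation). Among them was the glucose transporter Slc2a1 (79.0 ± 26.1 to 347 ± 80.1 CPM, 2.13, SE 0.26, adjusted p = 0.000749). The glycolysis median was 0.97, with 10 genes higher, without day 4 replicate 1 and 0.27 without day 4 replicate 2.

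Of the 75 nuclear oxidative phosphorylation genes 11 rose further with edgeR (median 0.50, camera adjusted p = 2.02e-06, or 0.751 with an estimated correlation and 0.133 with fry). Of the 75, 33 had an unadjusted p under 0.05 and 20 passed with DESeq2. The count of 11 was 6 with DESeq2's size factors, 19 with total counts and 24 with no filter. It was 2 without any one day 0 library, 41 without day 4 replicate 1, 0 without day 4 replicate 3 or day 8 replicate 2 (median 0.31) and 1 without day 8 replicate 1. Leaving out day 4 replicate 2 gave 5 higher and 1 lower with a median of 0.21. None of the 13 genes of the mitochondrial genome (median 0.23, adjusted p = 0.509) or the 19 of the tricarboxylic acid cycle (median 0.11, adjusted p = 0.555) passed with edgeR. At an unadjusted p under 0.05, 1 and 2 did, and with DESeq2 0 and 1. The tricarboxylic acid cycle median was -0.12 with 2 genes lower without day 4 replicate 2, and 0.30 with 2 higher without day 4 replicate 1. That of the mitochondrial genome was -0.11 without day 8 replicate 1, and 1 gene passed without day 4 replicate 1 or day 8 replicate 3. Mitochondrial ribosomal protein genes were higher in 10 of 76 cases and lower in 1, Mrpl36. The Mrpl36 call did not pass with only the 6 libraries compared (adjusted p = 0.0632) or without day 4 replicate 1 (0.056), day 4 replicate 3 (0.0845), day 8 replicate 1 (0.0848) or day 8 replicate 3 (0.0661). The list had a median of 0.19 (camera, adjusted p = 0.0224, or 0.88 with an estimated correlation and 0.285 with fry). Those higher included Mrpl23 (0.87, SE 0.17, adjusted p = 0.00638). That list did not pass without day 4 replicate 2 (median 0.02, adjusted p = 0.912) or day 8 replicate 2 (median 0.08, adjusted p = 0.342). Its count of changed genes was 7 without any one day 0 library, 20 with a median of 0.29 without day 4 replicate 1, 2 without day 4 replicate 3, 4 without day 8 replicate 1 and 3 without day 8 replicate 2.

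ATF4 and integrated stress response targets rose in 12 of 26 cases and fell in 1, the serine synthesis enzyme Psat1. The Psat1 call did not pass with no filter (adjusted p = 0.0643), with only the 6 libraries compared (0.0862) or without day 0 replicate 1 (0.05), day 4 replicate 3 (0.085), day 8 replicate 1 (0.0841) or day 8 replicate 2 (0.0765). The ATF4 targets' median was 0.71 (adjusted p = 1.05e-07; adjusted p = 0.212 with an estimated correlation; median 0.46 without day 4 replicate 2). The stress transcription factors Atf3 (4.71 ± 1.63 to 39.3 ± 4.95 CPM, 3.06, SE 0.33, adjusted p = 0.00039) and Ddit3 (65.1 ± 30.1 to 529 ± 90.2 CPM, 3.02, SE 0.30, adjusted p = 0.000305) were among them. Endoplasmic reticulum chaperones and folding factors rose in 9 of 18 cases (median 0.50, adjusted p = 4.24e-08; adjusted p = 0.212 with an estimated correlation). An example was Sdf2l1 (18.3 ± 4.72 to 90.1 ± 21.4 CPM, 2.30, SE 0.23, adjusted p = 0.000305). Interferon response genes rose in 13 of 16 cases (median 1.71, adjusted p = 7.4e-10; adjusted p = 0.212 with an estimated correlation; 7 higher without day 4 replicate 3). Irf7, the transcription factor that amplifies interferon production, stood at 9.45 ± 2.06 CPM at day 4 and 45.3 ± 9.98 CPM at day 8. Rsad2, the antiviral protein viperin, rose from 0.0914 ± 0.0238 to 3.91 ± 1.87 CPM (5.36, SE 0.60, adjusted p = 0.000463). Glucocorticoid targets fell in 5 of 12 cases, Fkbp5, Sgk1, Sult1a1, Tsc22d3 and Zbtb16. The median was -0.47 (adjusted p = 8.81e-07; adjusted p = 0.192 with an estimated correlation). Tsc22d3, an anti-inflammatory leucine zipper protein, went from 278 ± 29.1 to 68.1 ± 14.8 CPM (-2.03, SE 0.19, adjusted p = 0.000221).

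Cell cycle genes fell in 18 of 27 cases (median -0.93, adjusted p = 1.6e-09; adjusted p = 0.436 with an estimated correlation; 10 without day 8 replicate 1 and 9 without day 8 replicate 2). Among them were Mcm5 (-2.14, SE 0.28, adjusted p = 0.00105) and the mitotic cyclin Ccnb1 (-1.64, SE 0.29, adjusted p = 0.00398). Fibrillar matrix genes fell in 8 of 25 cases and rose for Thbs1 (median -0.65, camera adjusted p = 8.9e-05, or 0.616 with an estimated correlation and 0.0634 with fry). The Thbs1 call did not pass with total counts (adjusted p = 0.0642), with only the 6 libraries compared (0.0828) or without any one library (0.0589 to 0.125) other than day 4 replicate 2, where its log2 fold change was 2.57 in place of 1.63, and day 8 replicate 2. Elastin, Eln, went from 41.6 ± 7.69 to 7.45 ± 3.37 CPM (-2.48, SE 0.36, adjusted p = 0.00173). The matrix list had 2 higher and 12 lower with no filter, and its count was 5 without day 0 replicate 3 or day 4 replicate 3 and 4 without day 8 replicate 1 or day 8 replicate 2. In basement membrane Col4a1, Col4a2, Hspg2 and Lamc1 fell and Col15a1 rose. Lamc1 did not pass with only the 6 libraries compared (adjusted p = 0.0592) or without day 8 replicate 1 (0.0816) or day 8 replicate 2 (0.0788). Col15a1 did not pass with DESeq2's size factors (0.0503), total counts (0.0538), only the 6 libraries compared (0.0873) or without any one library (0.0539 to 0.142) other than day 0 replicate 1 and day 4 replicate 1. The basement membrane list's median was -0.43 (adjusted p = 0.00412; adjusted p = 0.538 with an estimated correlation; 3 changed without day 8 replicate 1 or day 8 replicate 2). The collagen IV chain Col4a2 went from 1778 ± 396.6 to 625 ± 114.9 CPM (-1.51, SE 0.21, adjusted p = 0.00128). Preadipocyte genes fell in 6 of 16 cases (median -0.60, camera adjusted p = 0.0393, or 0.724 with an estimated correlation and 0.199 with fry). The list did not pass with total counts (adjusted p = 0.0526), without day 8 replicate 2 (0.172, with 1 gene changed) or without day 4 replicate 2 (0.385, median 0.19 with 17 members tested). The count was 1 without day 8 replicate 1, and the median -0.39 with no filter (adjusted p = 0.0128).

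Cytosolic ribosomal protein genes fell in 9 of 79 cases (median -0.28, camera adjusted p = 4.97e-05, or 0.761 with an estimated correlation and 0.131 with fry). At an unadjusted p under 0.05, 23 were lower, and 18 passed with DESeq2. An example was Rpl10a (1034 ± 195.3 to 577 ± 106.8 CPM, -0.84, SE 0.19, adjusted p = 0.0117). The ribosomal count was 1 with a median of -0.18 without day 8 replicate 1, 14 with a median of -0.46 without day 8 replicate 2 and 2 without day 8 replicate 3. Ribosome biogenesis genes fell in 10 of 28 cases (median -0.33, adjusted p = 0.00124; adjusted p = 0.525 with an estimated correlation; 6 without day 4 replicate 3 or day 8 replicate 1). Among them was the nucleolar protein Nop56 (-1.14, SE 0.22, adjusted p = 0.0065). Translation factors went both ways (median -0.01, adjusted p = 0.557). The scaffold of the cap-binding complex, Eif4g1, fell from 530.0 ± 47.6 to 290 ± 12.2 CPM (-0.87, SE 0.13, adjusted p = 0.00195) along with Eef1b2 and Eif4g3. The helicase Eif4a2 rose from 119 ± 37.5 to 258.5 ± 41.2 CPM (1.12, SE 0.23, adjusted p = 0.00749). The tryptophanyl-tRNA synthetase Wars rose (0.92, SE 0.13, adjusted p = 0.00158), while the list of 20 synthetases did not pass with camera (median 0.16, adjusted p = 0.184) and did with fry (0.0197).

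The other lists did not pass with camera between days 4 and 8. None of the 15 contractile genes passed with edgeR (median 0.31, adjusted p = 0.415). At an unadjusted p under 0.05, 2 were higher and 1 lower, and 1 and 1 passed with DESeq2. When day 4 replicate 2 was left out, 11 rose (median 1.16, adjusted p = 1.81e-08). Medians were 0.24 for fatty acid oxidation (Hadhb higher, Cpt1a lower of 18; adjusted p = 0.509) and -0.09 for branched-chain amino acid breakdown (Acat1, Bcat2 and Mccc2 lower of 20; adjusted p = 0.643). They were 0.15 for the energy-dissipating cycles (Ckb higher, Gamt lower of 7; adjusted p = 0.547), and -0.01 for cholesterol synthesis (Cyp51, Dhcr7, Hsd17b7 and Nsdhl lower of 21; adjusted p = 0.112). Fatty acid synthesis had a median of 0.15 and a mean of -0.23 (adjusted p = 0.554), with Fads1 and Fads2 higher and Acaca, Acly, Fasn, Srebf1 and Thrsp lower. Fatty acid synthase, Fasn, fell from 3211 ± 894.5 to 1524 ± 220.1 CPM (-1.08, SE 0.23, adjusted p = 0.00868). The peroxisome median was 0.004 with TMM scaling and -0.024 with total counts, with the test's direction down (Abcd3 and Acaa1b higher, Ehhadh and Hsd17b4 lower of 18; adjusted p = 0.812). The inflammatory cytokine median was likewise 0.04 and -0.03, with a mean of 0.34 and the direction down (Il6 and Ptgs2 higher, Lcn2, Nfkbia and Tnfaip3 lower of 14; adjusted p = 0.878). The cytokine median was 1.07 without day 4 replicate 2 (4 higher, 3 lower; adjusted p = 0.14) and that of fatty acid oxidation 0.03 (1 higher, 3 lower). Leaving out day 4 replicate 1 gave medians of -0.28 for cytokines, 0.09 for branched-chain amino acid breakdown (3 higher, 3 lower), -0.11 for the energy-dissipating cycles and 0.10 for contractile genes (2 lower). The cytokine median was -0.11 without day 4 replicate 3 and -0.19 without day 8 replicate 3. Some of these single genes did not pass in other fits. This held for Hadhb (adjusted p from 0.0604 to 0.0785) and Lcn2 (0.0512 to 0.0678) without day 4 replicate 3, day 8 replicate 1 or day 8 replicate 2. It held for Acat1 (0.0656 to 0.0825) and Fads2 (0.0689 to 0.105) without day 4 replicate 3, day 8 replicate 2 or day 8 replicate 3, and for Thrsp (0.0541 to 0.0669) without day 4 replicate 3, day 8 replicate 1 or day 8 replicate 3. Cpt1a did not pass without any one day 0 or day 8 library (0.0506 to 0.106), Abcd3 without any one library but day 4 replicate 1 (0.064 to 0.152), and Il6 without any one but day 8 replicate 2 (0.0534 to 0.124). Hsd17b4 did not without day 0 replicate 2, day 4 replicate 1 or 3 or any one day 8 library (0.0525 to 0.105), nor Hsd17b7 without day 0 replicate 3, day 4 replicate 2 or 3 or day 8 replicate 1 or 2 (0.0516 to 0.115). With only the 6 libraries compared Abcd3, Acat1, Cpt1a, Fads2, Hadhb, Hsd17b4 and Hsd17b7 did not pass (0.0565 to 0.115), nor did Hsd17b7 with total counts (0.0517) or Abcd3 with DESeq2's size factors (0.0574). With day 4 replicate 2 left out, fatty acid synthesis (median -0.13, adjusted p = 0.00113), branched-chain amino acid breakdown (-0.27, adjusted p = 0.0129) and peroxisomes (-0.20, adjusted p = 0.0382) passed as lower. Cholesterol synthesis passed without day 8 replicate 3 (adjusted p = 0.034). Adjusted over the list alone, the counts of the lists that passed were the same for preadipocyte genes and for the 13 higher interferon genes. They were 0 for oxidative phosphorylation and cytosolic ribosomal proteins, and 7 higher and 1 lower for mitochondrial ribosomal proteins. They were 9 higher and 1 lower for thermogenic genes, and 8 for glycolysis. They were 14 higher and 1 lower for ATF4 targets, 11 for chaperones, 6 for glucocorticoid targets, 24 for cell cycle, 1 higher and 12 lower for fibrillar matrix, 1 higher and 6 lower for basement membrane and 11 for ribosome biogenesis. Among lists that did not pass, counts so adjusted differed for fatty acid oxidation, with 0 by edgeR. It had 6 higher and 2 lower at an unadjusted p under 0.05, and 2 and 1 with DESeq2 adjusted over all genes. Counts also differed for synthetases (5 higher, 2 lower), translation factors (2 higher, 3 lower) and inflammatory cytokines (3 higher, 3 lower). Endothelium had 2 lower and skeletal muscle 2 higher.

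Genes were then sorted by their calls in both intervals, day 0 to 4 and day 4 to 8, to separate transient from continued changes. Among 625 genes that rose and then fell were Map7d2 (0.0476, 59.1 and 1.31 CPM at days 0, 4 and 8) and the sulfotransferase Sult1a1 (0.253, 125 and 10.9 CPM). Among 455 that fell and then rose were Ptgs2, the inducible cyclooxygenase (13.9, 0.189 and 3.06 CPM), and Car6, a secreted carbonic anhydrase (13.1, 1.73 and 18.1 CPM). Among 523 that rose in both intervals were Cidea and Ucp1. Among 355 that fell in both was Slit2, a guidance ligand (189, 30.0 and 5.76 CPM). Independent lists of the same sizes would share 451, 444, 489.1 and 409.5 genes in these 4 classes. Both comparisons use the day 4 libraries. In 20 simulations of unchanged groups no gene entered any class with edgeR. At an unadjusted p under 0.05 a mean of 154 had opposite and 1.15 the same direction. With 3 day 4 libraries neither part of a split keeps 2, so part of any excess may come from the shared libraries.

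The class counts moved with single libraries. The total of 1958 was 980 without day 4 replicate 3, 1253 without day 8 replicate 1 and 1224 without day 8 replicate 2. Genes that rose and then fell numbered 345 without day 4 replicate 3, and genes that rose in both intervals 318, 348 and 323 without day 0 replicates 1, 2 and 3, 241 without day 4 replicate 3 and 259 without day 8 replicate 2. Genes that fell and then rose numbered 302 and 300 without day 0 replicates 2 and 3, 723 without day 4 replicate 2, 213 without day 4 replicate 3 and 296 without day 8 replicate 1. Genes that fell in both numbered 217, 222 and 214 without day 0 replicates 1, 2 and 3, 548 without day 4 replicate 1, and 181 without day 4 replicate 3. They numbered 169 without day 8 replicate 1 and 132 without day 8 replicate 2. Without day 4 replicate 2 the log2 fold changes of Slit2 were -3.37 and -1.71 in the 2 intervals in place of -2.66 and -2.38, and those of Gxylt2 -4.07 and -1.61 in place of -3.31 and -2.32.

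Lists of markers of other cell types that a culture from fat can hold did not pass with camera in any comparison. Against day 0 fry called mural cells (adjusted p = 0.00015 at day 4, 0.000149 at day 8) and Schwann cells (0.0267 and 0.00322) as higher. It called skeletal muscle as lower at day 4 (0.00493) and as higher from day 4 to 8 (0.0395). At day 4 against day 0 the macrophage median was 0.16 with TMM scaling and -0.15 with total counts, with the test's direction down (Mrc1 higher of 13; adjusted p = 0.799). The endothelial median was -1.13 (Egfl7 higher, Emcn and Tek lower of 6; adjusted p = 0.755). The mural cell median was 0.35 (Cspg4, Mcam and Steap4 higher of 7; adjusted p = 0.143), the Schwann cell median -0.23 with a mean of 0.24 (Mbp and S100b higher of 5; adjusted p = 0.709) and the skeletal muscle median -3.22 (Acta1 and Tnnt3 lower of 3; adjusted p = 0.118). For macrophages, endothelium, mural cells, Schwann cells and muscle, in this order, medians at day 8 against day 0 were -0.66 (adjusted p = 0.295), -2.43 (0.48), 0.57 (0.316), 0.63 (0.554) and -1.78 (0.541). At day 8 against day 4 they were -0.21 (0.0703), -1.19 (0.237), 0.40 with a mean of 0.01 and the direction down (0.554), 0.65 (0.555) and 1.43 (0.0946). With the library in parentheses left out, medians at day 4 against day 0 spanned -0.19 (day 0 replicate 1) to 0.30 (day 0 replicate 2) for macrophages, -1.99 (day 4 replicate 2) to -0.71 (day 0 replicate 2) for endothelium, -0.06 (day 4 replicate 3) to 0.59 (day 0 replicate 2) for mural cells and -0.49 (day 0 replicate 2) to 0.71 (day 0 replicate 3) for Schwann cells, and muscle reached -4.20 (day 4 replicate 2). At day 8 against day 0 macrophages spanned -1.12 (day 8 replicate 3) to -0.19 (day 8 replicate 1), mural cells reached -0.23 with 9 members tested (day 4 replicate 2; -0.17 without either other day 4 library), and without day 8 replicate 3 endothelium was at -3.16 and Schwann cells at -0.02. Between days 4 and 8 macrophages spanned -0.88 (day 8 replicate 3) to -0.06 (day 8 replicate 1), endothelium -2.02 (day 8 replicate 3) to -0.65 (day 4 replicate 2), and mural cells reached -0.17 (day 4 replicate 3), Schwann cells 0.33 and muscle 2.20 (day 4 replicate 2 for both). At day 4 against day 0, Mrc1 did not pass without day 0 replicate 1 or 2 or day 4 replicate 3 (adjusted p from 0.0692 to 0.0976), nor Emcn with no filter (0.0595) or without day 0 replicate 2 or 3 or any one day 4 library (0.053 to 0.107). Tek did not without day 0 replicate 1 or 3, day 4 replicate 1 or 3 or day 8 replicate 1 or 2 (0.0521 to 0.126), nor Cspg4 with total counts (0.0822) or without day 0 replicate 1 (0.063) or day 4 replicate 1 (0.061). S100b did not with total counts (0.224) or without day 0 replicate 1 or 2, day 4 replicate 2 or day 8 replicate 2 or 3 (0.0563 to 0.185), and Tek (0.0753) and S100b (0.065) did not with only the 6 libraries compared. Adjusted over the list alone, the day 4 counts differed for macrophages (0 with edgeR; 1 higher and 1 lower both at an unadjusted p under 0.05 and with DESeq2 adjusted over all genes) and Schwann cells (1 higher). The macrophage list passed as lower between days 4 and 8 with no filter on low counts (adjusted p = 0.0255) and without day 0 replicate 1 (adjusted p = 0.0486), day 8 replicate 2 (0.0194) or day 8 replicate 3 (0.00685), and the skeletal muscle list as higher without day 4 replicate 2 (0.00247). The lymphocyte, mesothelial and mammary epithelial lists had 1, 2 and 0 members with enough counts and were not tested as lists. The most abundant marker of each type at its highest day was Lyz2 at 49.2 CPM for macrophages, Egfl7 at 25.3 for endothelium, Steap4 at 147 for mural cells, and Krt19 at 39.3 for mesothelium. It was Acta1 at 32.9 for muscle, Mbp at 17.1 for Schwann cells, Lck at 2.24 for lymphocytes and Trp63 at 0.305 for mammary epithelium.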

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

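The 7 tests of explanations for the 3 patterns weighed here were chosen only after the results were seen, while the counts over other splits of the samples were planned.

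The comparison of day 8 with day 4 is also the test of whether the effects at these times against day 0 differ, and 14 lists passed it. Their median log2 fold changes from day 4 to day 8 were 1.05 for thermogenic genes, -0.60 for preadipocyte genes, -0.65 for fibrillar matrix, -0.43 for basement membrane, -0.93 for cell cycle, 0.50 for nuclear-encoded oxidative phosphorylation, 0.62 for glycolysis, 0.71 for ATF4 targets, -0.28 for cytosolic ribosomal proteins, 0.19 for mitochondrial ribosomal proteins, -0.33 for ribosome biogenesis, 0.50 for endoplasmic reticulum chaperones, -0.47 for glucocorticoid targets and 1.71 for interferon response. None of the 14 passed with an estimated correlation, where the lowest adjusted p was 0.192 and 4 lists had an unadjusted p under 0.05; fry called 11 lists in this comparison. Without day 4 replicate 2 the preadipocyte median was 0.19, and that list and mitochondrial ribosomal proteins (0.02) did not pass.

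Day 4 replicate 2 lay between day 0 and the other day 4 libraries. Cells that stayed as at day 0 would leave the same share of day 0 transcripts as they withhold of induced ones, but 89 genes that fell in the other day 4 libraries kept a median of 6.55% of their day 0 level (quartiles 2.69 to 10.4) while 232 risen genes were short by 47.4% (35.7 to 58.8), which argues against that mixture. A library of another day is argued against by 41 genes high at day 4, which stood a median log2 of 1.98 above the higher of days 0 and 8 (first quartile 1.24), and low depth by its total of 27692241 counts, the highest of day 4 (27.7 in units of 1e6). A culture that differentiated less far remains an untested hypothesis.

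Interferon response genes were low at day 4 and higher again at day 8. Fewer macrophages at day 4 would lower their markers as well, but the macrophage median was 0.164 (first quartile -0.402; -0.19 without day 0 replicate 1) against -1.85 for the interferon list. Scaling between libraries is argued against by the smaller of the 2 intervals' medians, 1.64 in size over 3 scalings. Dexamethasone, IBMX and indomethacin were all left out of the medium after 2 days, so their withdrawal came before day 4 and not between days 4 and 8. A lasting or delayed effect of these drugs is confounded with time and was not tested.

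Genes of mitochondrial proteins rose together by day 4. The oxidative phosphorylation genes are short, with a median length of 1140 bases, but after the trend over length and GC content was removed their median log2 fold change was 2.01 (first quartile 1.67), while that of the ribosomal proteins, as short at 1060, went from 0.08 to -0.40; this argues against length or GC bias as the whole cause. The lowest median over 3 scalings was 2.09, which argues against scaling. A rise in mitochondrial content with differentiation is a hypothesis that counts of RNA cannot test.

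Splits of 3 against 3 libraries number 10, too few for a share under 0.05. For genes called by edgeR, the real splits gave 7998, 9290 and 3285 in the 3 comparisons. Each time 1 of 10 was as large and the highest other was 0. At an unadjusted p under 0.05 other splits gave up to 596, 332 and 1795. For gene lists adjusted within a comparison, real splits gave 17, 17 and 14 and other splits up to 20, 21 and 20. With 6, 7 and 7 of 10 as large, counts of passing lists did not set the real days apart. For genes changed in both intervals, 2 of 100 groupings gave as many as the real 1958. The other, with 5929, had the 3 day 0 libraries as its middle group. All 99 others mixed days within groups, which widens the spread, so chance is not excluded.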

How the results depend on the processing

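The alternatives were planned except the counts of list members without day 4 replicate 2, the calls of single list members under each setting and the bounds and ratios over 0 to 3 counts without each library, which were chosen after the data were seen. With the estimated correlation and fry set apart, 1248 list results (1215 with the same call, 15 no longer past the threshold, 18 newly past it) and 6563 results of named genes (6248, 304 and 11) held no reversed direction where either fit passed the threshold. Where neither did, the test's direction turned in 23 list results and the fold change in 9 gene results. Medians turned sign in 56 list results, 3 of them with a call in either fit, all at day 8 against day 4 without day 4 replicate 2: preadipocyte genes (-0.60 to 0.19, the test still down), fatty acid synthesis (0.15 to -0.13) and peroxisomes (0.004 to -0.20). Leaving out 1 library at a time gave 6613 to 9110 changed genes at day 4 against day 0 (3602 to 4560 higher, 2916 to 4550 lower), 8323 to 10111 at day 8 against day 0 (4330 to 5037 higher, 3976 to 5074 lower), and 1894 to 4185 at day 8 against day 4 (910 to 2049 higher, 929 to 2136 lower). Genes changed in both intervals numbered 980 to 2449, with 345 to 905 that rose then fell, 213 to 723 that fell then rose, 241 to 642 that rose in both and 132 to 548 that fell in both. Lists numbered 16 to 18, 16 to 18 and 13 to 18. These fits hold fewer samples; beyond that the cause was not tested.

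With DESeq2's size factors edgeR called 8041, 9273 and 3252 genes in the 3 comparisons, with no filter 7970, 9360 and 3489, and DESeq2's Wald test called 8422, 9555 and 4254, with 628 genes that fell in both intervals; the cause was not tested. Fits of only the 6 libraries compared called 1901 genes at day 8 against day 4, 947 higher and 954 lower, with fewer samples to estimate the spread. Testing against a fold change of 2 asks for larger effects and called 3070 genes at day 4 against day 0 (1903 higher, 1167 lower), 4275 at day 8 against day 0 (2411 and 1864) and 257 at day 8 against day 4 (162 and 95). With an estimated correlation camera called 0, 0 and 0 lists (7, 6 and 4 at an unadjusted p under 0.05), and fry called 26 at day 4 against day 0. Of 96 list results, 48 were no longer past the threshold with the estimated correlation, and with fry, which asks another question, 6 were not and 17 newly were.

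Same-numbered replicates correlated from -0.126 to 0.273 in their deviations from the group means, 2 of 9 pairs lay over 0.1, and 5 of 9 libraries correlated best with their own number, so the numbers were not taken to pair the samples. With the replicate number as a block there were 8070, 9368 and 3105 changed genes, 1829 changed in both intervals, and 17, 17 and 16 lists; macrophage markers (adjusted p = 0.0311) and skeletal muscle markers (0.0462) passed at day 8 against day 4, no other list call changed (at day 8 against day 4 the preadipocyte median was -0.39 and 4 oxidative phosphorylation genes passed), and 13 calls among 438 results of genes named by the rule did not pass. Simulated 1.5-fold changes were recovered in 8% and 6% of genes against day 0, so small changes can be missed. Only 200 genes were changed there, so rates may differ here.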

Other observations

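The 4 gene lists here were chosen after the data had been examined, and the test of imprinted genes was written after its result was seen, the tests of the other 3 lists before theirs. Their p-values are from limma's camera, adjusted over 12 tests.

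Hypoxia targets, genes induced when oxygen is low, rose from day 4 to day 8 in 8 of 19 cases, with none of the list falling by edgeR. Car9, a carbonic anhydrase, went from 0.607 ± 0.233 to 10.1 ± 1.5 CPM (log2 fold change 4.06, SE 0.32, adjusted p = 0.000128, n = 3 per day), and Ndrg1, a stress-responsive protein, from 17.6 ± 5.95 to 101 ± 23.9 CPM (2.52, SE 0.27, adjusted p = 0.000372). The hypothesis was that the rise of glycolysis genes in this interval is shared by hypoxia targets, on a list with no gene of the glycolysis list. The list's median was 0.956 (quartiles 0.541 to 1.31, adjusted p = 8.72e-08, or 0.469 with an estimated correlation). It was 0.635 with 9 genes higher without day 4 replicate 2. This is consistent with a shared response, but it does not show that the cells lacked oxygen.

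Genes of class I antigen presentation rose in the same interval in 10 of 14 cases, among them the immunoproteasome subunit Psmb9 (2.55 ± 0.332 to 20.5 ± 3.86 CPM, 3.00, SE 0.25, adjusted p = 0.000154) and the class I heavy chain H2-K1 (337 ± 74.0 to 661 ± 102 CPM, 0.97, SE 0.19, adjusted p = 0.00605), whose reads can be shared with related genes. Their median was 0.968 (adjusted p = 2.23e-11; adjusted p = 0.228 with an estimated correlation). At day 4 against day 0 it was 0.196 (quartiles -0.123 to 0.623), while interferon response genes fell, so whether both lists follow a common signal over the whole course remains open.

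Imprinted growth genes did not all fall in both intervals, and whether the list does so as a group remains open. The noncoding RNA Rian fell in both, from 221 ± 14.1 to 46.7 ± 37.1 and 9.62 ± 4.13 CPM (-2.24, SE 0.49, adjusted p = 0.0029, and -2.28, SE 0.50, adjusted p = 0.0104; without day 4 replicate 2, -3.12 and -1.44), but Mest, a hydrolase-like protein, rose from 1.18 ± 0.0978 to 22.5 ± 8.11 CPM by day 4. At day 4 against day 0 the list had 9 of 18 genes lower and 4 higher with a median of -0.91, and its adjusted p of 0.144 was the higher of the intervals. At day 8 against day 4 the median was -0.92 with 6 genes lower (adjusted p = 0.00461, or 0.544 with an estimated correlation). The list passed as lower in both intervals without day 4 replicate 2 (median -0.99, 11 lower and 4 higher, adjusted p = 0.0481, and median -0.67, adjusted p = 0.0238). Lysosome genes had 4 higher and 2 lower of 26 between days 4 and 8 (adjusted p = 0.906), with the cholesterol transporter Npc1 (30.7 ± 2.69 to 77.8 ± 6.70 CPM) and the acid lipase Lipa (68.1 ± 14.7 to 140 ± 23.8 CPM) among those higher.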
